A study of Escherichia coli with 8 samples.

How the data were processed

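RNA was sequenced from 8 cultures of E. coli BW25113 ΔacrB, 2 biological replicates in each of 4 groups: tedizolid at 20 µg/mL, DMSO collected with it, delpazolid at 80 µg/mL, and DMSO collected with that. Cultures were treated for 2.5 min at 10 times the minimal inhibitory concentration, with 2% DMSO throughout, per the labels' protocols. Per the labels' protocols, RNA was depleted of small RNA and ribosomal RNA, fragmented, and size-selected on gels before linker ligation, reverse transcription and circularization. Fragments of 20 to 100 nt were kept. Some very short genes rested on few reads, such as the leader peptide trpL on 0 to 10 per library. The small-protein gene azuC had 232 to 2531.

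The submitters' processing notes name cutadapt 4.4, Bowtie (no version) and FastQC, with no role or order. Genome build, annotation, mismatch settings and the denominator of the scaling are not given in the sources used here. Gene identifiers in the deposited tables carry BW25113 locus tags. Per the file headers, the authors gave RPKM (reads per kilobase of gene, scaled to library size) for each RNA library, in 1 table per experiment. The same tables hold the authors' log2 fold change of translation efficiency and its adjusted p-value, per the file headers; no translation efficiency was recomputed here, and 16 further columns of footprint or efficiency values per library were not used. Tables that hold a filtered subset of the same genes were not used here. The values of both experiments were compared on the authors' scaling, which was applied per library.

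Before any test, the low values were checked for the size of 1 read. RPKM times gene length took whole multiples of a single step in each library: 99.42% to 99.69% of low values lay within 0.1 of a whole number of reads. Lengths came from a table of the MG1655 assembly ASM584v2, which held a length for 4130 of the 4131 genes and listed 3881 of them under the same symbol; it served for lengths, names and gene order, and no coordinates are printed. The steps gave 4756016 reads for the shallowest library, DMSO replicate 1 of the delpazolid experiment, and 7661074 reads for the deepest, tedizolid replicate 2. Read numbers are estimates. P-values rest on the spread between cultures, pooled in part over genes, and not on counting error. The 10 genes with the most reads, taken as RPKM times gene length, held 15.53% to 16.61% of the reads summed over genes. Whether the authors assigned reads by strand is not given in the sources used here. Genes that overlap another or have an antisense partner, and near-identical families, may therefore share reads. No replicate pair within a group was close enough to be a duplicate, since its chi-square per degree of freedom was 6.59 at the lowest; libraries of different groups were not compared in this way.

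The design was fixed before the data were examined, with a count test for counts and a log-scale test for normalized values; the values were RPKM, so the second was used and no count-based test of the deposited values was run. Genes with a mean of at least 1 RPKM over the 8 libraries (4026) were tested with limma 3.58.1 in R 4.3.3, as a moderated test with an intensity trend on log2(RPKM + 1). Fold changes are on that scale, which understates the change of low genes. The leading fit held 8 libraries and 4 group means (4 residual degrees of freedom), and an alternative fixed with it fitted each drug with its own DMSO libraries alone (2 residual degrees of freedom). Contrasts were each drug minus its own DMSO, the difference of these responses, and DMSO against DMSO. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05, and intervals are 95% intervals from the same fit. Cultures grew from individual colonies per the labels.

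29 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists of a contrast. Camera with a correlation estimated from the data stood beside it, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Lists with fewer than 5 measured members would not have been tested.

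Named genes were chosen by a rule fixed before the data were examined. For each drug, it takes the 10 largest changes each way among called genes with a mean of at least 10 RPKM in that experiment and the same direction in both replicate pairs, or, where none passes, the 5 each way with the smallest p. For the difference it takes 5 each way by the same rule, and for each list up to 4 members with the smallest p. For tedizolid the rule was applied to the calls and p-values of the 4-library fit, a choice made after the spread between replicates had been seen. acrB, acrA, acrD, acrF, tolC, rmf, cspA and the first enzyme gene after a named leader peptide are always given. Genes named outside it were chosen after their values were seen: the 10 genes called between DMSO libraries, the purine genes purF, purE and guaB and the ribosomal genes ykgM and ykgO under tedizolid, the 13 genes that differed without the libraries labelled replicate 2 of the delpazolid experiment, and the operon genes of the closing part.

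The labels say that each DMSO replicate of the tedizolid experiment was collected with the drug culture of the same number, so the numbers pair these libraries. In the check of that pairing, deviations from the group means correlated across genes at 0.162 between same-numbered libraries of the tedizolid experiment and at −0.109 in the delpazolid experiment. For the latter the titles place both DMSO cultures with drug replicate 1, so the pairing of its replicate 2 is not settled by the labels. In each experiment the sample descriptions name the replicate 1 column for both DMSO libraries. The DMSO columns were therefore matched by library name, against that note for replicate 2. Libraries are named here as labelled throughout.

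Alternatives fixed in advance were median-ratio scaling, no rescaling beyond library totals (identical to the leading fit, since RPKM is already scaled), no filter, a filter at 5 RPKM, no intensity trend, each drug with its own DMSO libraries, the replicate block, pseudocounts of 0.1 and 10, all 4 DMSO libraries as one control, a 1.5-fold minimum change, and each library left out in turn. Added after the data were seen were fits without both libraries labelled replicate 2 of the delpazolid experiment, limma-voom on recovered reads, array weights, a crossed pairing, and the settings above within the 4-library tedizolid fit.

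The fits were tested on simulated data for the 4026 genes, with 100 genes changed 2-fold and 100 changed 4-fold. With each group's measured spread, the 8-library fit recovered 2 and 85 of these for tedizolid and the 4-library fit 72 and 95, with 0 and 5 false calls. For delpazolid the 8-library fit recovered 17 and 83 with 37 false calls among 3786 unchanged genes. With the tedizolid experiment's spread in every group, the 8-library fit recovered 72 and 92 for tedizolid and 69 and 95 for delpazolid. The shifted gene list was called in all simulations and 0 of 28 unchanged lists were. Simulated genes were drawn independently of each other, so this does not test list calls where genes vary together.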

Results

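Messenger RNA was sequenced from 8 cultures of Escherichia coli BW25113 ΔacrB, a laboratory strain that lacks AcrB, the inner-membrane transporter of the main multidrug efflux pump. Log-phase cultures in rich defined medium received tedizolid at 20 µg/mL, delpazolid at 80 µg/mL or the solvent DMSO alone, at 2% in every culture, and were collected after 2.5 min. Each drug stood at 10 times its minimal inhibitory concentration, so the drugs were matched in that multiple and in time, while their µg/mL differed. Tedizolid and delpazolid are oxazolidinones, antibiotics that bind the large ribosomal subunit and inhibit protein synthesis. Both carry a hydroxymethyl group on the oxazolidinone ring; the outer part of tedizolid is a pyridine with a methyltetrazole, and that of delpazolid is a cyclic amidrazone. The series asks how the structure of such a drug shapes where on a message it halts the ribosome, and the RNA libraries give the transcript levels against which ribosome footprints are set.

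The libraries formed 4 groups of 2 biological replicates: tedizolid, the DMSO cultures of the tedizolid experiment, delpazolid, and the DMSO cultures of the delpazolid experiment. Their values were the authors' RPKM (reads per kilobase of gene, scaled by the authors to library size) for 4131 genes, of which 4026 had a mean of at least 1 RPKM and were tested. Depth estimated from the steps between low values was 7354023 and 7661074 reads for tedizolid and 6734914 and 7608034 reads for its DMSO libraries. It was 7501875 and 6936256 reads for delpazolid and 4756016 and 6800408 reads for its DMSO libraries. The deleted gene acrB lay between 0.373 and 0.778 RPKM in the 8 libraries (6 to 17 estimated reads), while acrA, its operon partner, lay between 324.6 and 659.6 RPKM (2021 to 6034 reads).

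Replicates agreed closely in the tedizolid experiment and poorly in the delpazolid experiment. Across genes, replicate log2 levels correlated at 0.993 for tedizolid, 0.993 for its DMSO libraries, 0.977 for delpazolid and 0.962 for its DMSO libraries. The chi-square of the recovered reads per degree of freedom was 6.59, 12.2, 74.1 and 113.2 in the same order, so every pair differed by more than sampling noise. The change from DMSO to drug in tedizolid replicate 1 correlated across genes at 0.84 with that in tedizolid replicate 2 and at 0.776 with that in delpazolid replicate 1. The change between the libraries labelled delpazolid replicate 2 and DMSO replicate 2 ran the other way, at −0.561 with tedizolid replicate 1, −0.529 with tedizolid replicate 2 and −0.492 with delpazolid replicate 1. Genes are not independent replicates, so these correlations across genes carry no p-value.

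**Figure D1:**
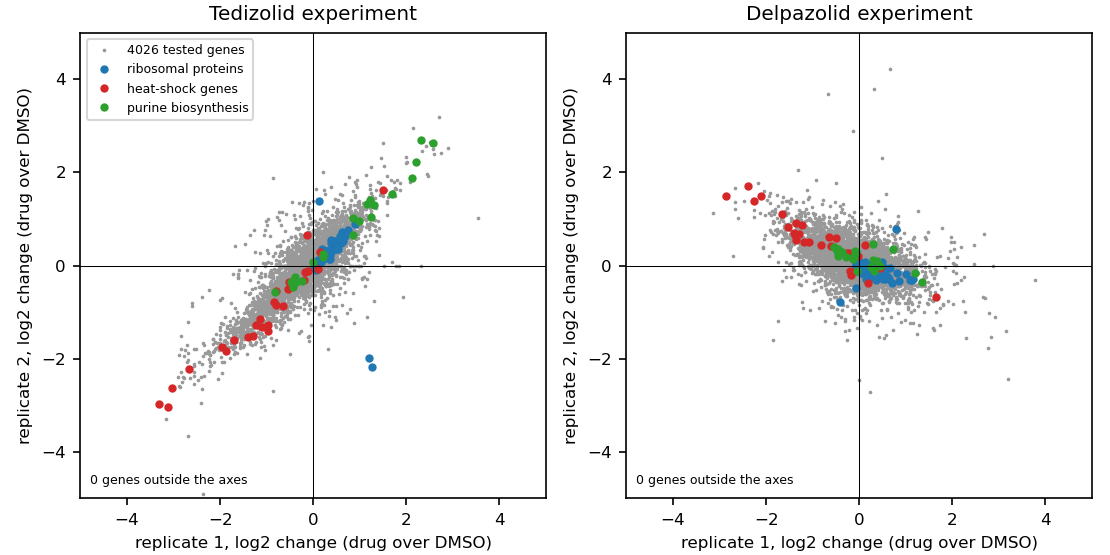
Change from DMSO to drug (log2 ratio of RPKM + 1) in replicate 1 (horizontal) against replicate 2 (vertical) for the tedizolid experiment (left) and the delpazolid experiment as labelled (right); each point is one of 4026 tested genes, with 3 gene lists coloured. The tedizolid pairs fall along a rising diagonal (r = 0.84) and the delpazolid pairs along a falling one (r = −0.492); the pair of ribosomal protein genes far below the diagonal on the left are ykgM and ykgO.

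The first comparison asked which transcripts changed in the first minutes of tedizolid. At a preset correlation between genes, the lists of ribosomal proteins, phage shock, purine synthesis and the mar regulon shifted higher, and those of heat shock, amino acid synthesis, central metabolism, respiration, flagella and sugar catabolism lower, with genes in every list that did not pass. With a correlation estimated from the data, 0 lists passed. Fitted on the 4 libraries of this experiment, limma called 1784 of 4026 genes, 631 higher and 1153 lower (2002 genes at an unadjusted p under 0.05). The fit of all 8 libraries, fixed as the leading design, called 3 genes, all higher: purM, xanP and purC (1128 genes at an unadjusted p under 0.05). It gives the 4 groups a single spread per gene, to which the delpazolid experiment contributed. Both fits were written down before the data were examined; the genes and lists below are called by the 4-library fit, chosen for this role once the replicate spread had been seen. With the replicate number as a block, the 8-library fit called 0 genes (936 at an unadjusted p under 0.05). Left-out libraries moved the 8-library count as well: it was 986 without DMSO replicate 1 of the delpazolid experiment, 989 without DMSO replicate 2 of that experiment, and 0 without any one of the other 6 libraries. Median-ratio scaling split the calls of the 4-library fit 815 higher and 965 lower (45.8% higher, against 35.4%), and moved the median change of all genes from −0.11 to 0.02 on the log2 scale. Against a minimum change of 1.5-fold, 510 of the genes passed, 138 higher and 372 lower.

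The largest increase was that of alaE (BW25113_2670), an exporter of L-alanine, from 26.5 ± 7.76 to 206.5 ± 9.74 RPKM (mean ± SD, n = 2), a log2 change of 2.94 ± 0.19 (SE; limma, adjusted p = 3.47e-06). arfA (BW25113_4550), which frees ribosomes stalled on truncated messages, went from 48.7 ± 6.61 to 325 ± 15.4 RPKM. purM (BW25113_2499), a purine synthesis enzyme, went from 92.3 ± 6.62 to 564.6 ± 22.7 RPKM, with a log2 change of 2.60 ± 0.10 (limma, adjusted p = 2.56e-07). The xanthine permease gene xanP (BW25113_3654) rose by 2.51 ± 0.17 and marR (BW25113_1530), repressor of the marRAB operon, by 2.54 ± 0.10. The magnesium transporter gene corA rose from 185.7 ± 17.9 to 1043 ± 24.5 RPKM. The small-protein gene azuC (2.49), yjcB (2.59), yicG (2.58) and yjeV (2.55, on 5 to 97 reads per library) completed the 10 largest increases.

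**Figure D2:**
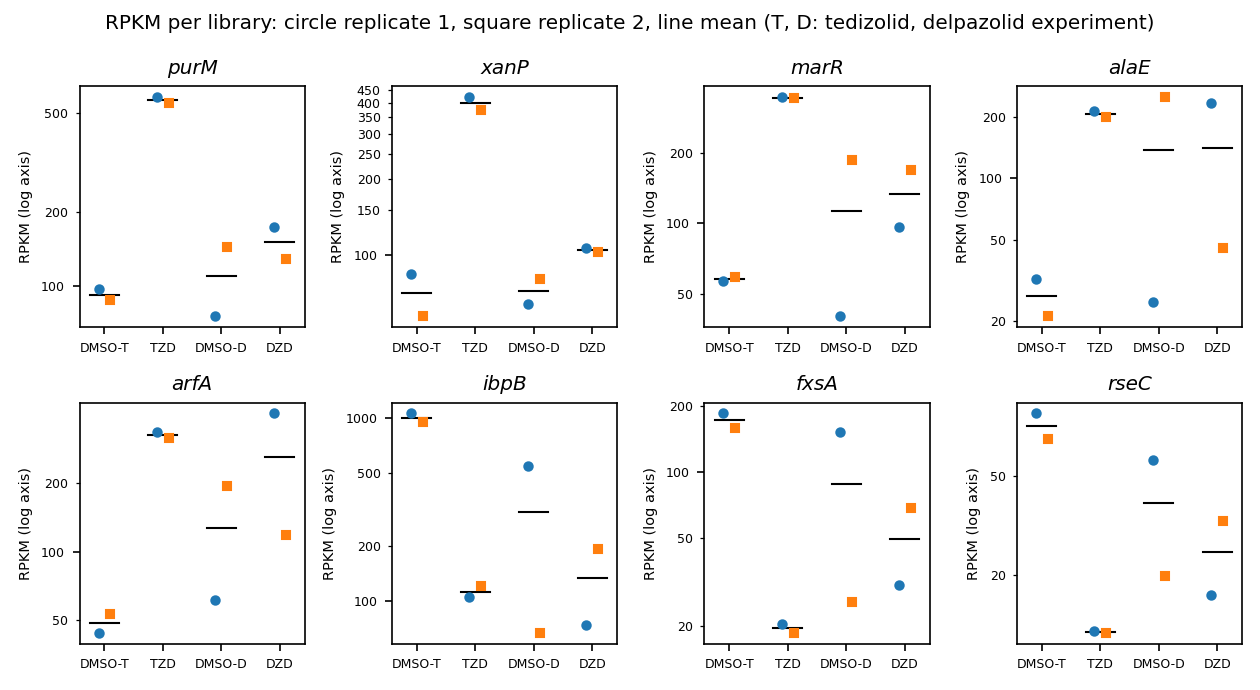
RPKM of 8 genes in each library on a log axis (circle, replicate 1; square, replicate 2; line, mean) for DMSO of the tedizolid experiment (DMSO-T), tedizolid (TZD), DMSO of the delpazolid experiment (DMSO-D) and delpazolid (DZD). The tedizolid libraries stand apart from their DMSO libraries for every gene shown. In every gene but xanP, the delpazolid experiment's libraries labelled replicate 2 lie in the opposite order to those of replicate 1. The reversed gap is small in purM and marR.

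Among the decreases, the log2 changes of the small heat-shock chaperone genes ibpB and ibpA were −3.14 ± 0.10 and −2.83 ± 0.10, ibpB going from 1004 ± 76.8 to 112.9 ± 11.2 RPKM (limma, adjusted p = 2.03e-07). The inner-membrane protein gene fxsA changed by −3.07 ± 0.15. rstB, a sensor kinase gene, stood at −2.73 ± 0.21, npr, a phosphocarrier gene, at −2.68 ± 0.19, and rseC at −2.66 ± 0.18. yliF and yfcA stood at −2.74 and −2.66. The largest fitted decreases rested on few reads: trpL, the leader peptide of the tryptophan operon, stood at −3.64 ± 0.55 on 0 to 10 reads per library, and ibsC at −3.18 ± 0.37 on 1 to 20 reads. ibsC belongs to a family of near-identical small toxin genes, so its value is uncertain. trpE, the first enzyme gene after trpL, stood at −0.98 ± 0.29, and at −0.73 without tedizolid replicate 2, where it was not called.

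Ribosomal protein genes rose as a group: 46 of 57 measured genes passed higher and 0 lower. Their median log2 change was 0.38, against −0.11 for all genes (limma camera, adjusted p = 3.37e-20). Adjusted over the list alone, 47 genes passed higher; for each list below, the counts adjusted over the list alone were the same as those over all genes unless given. With a correlation between genes estimated from the data, none of the 14 lists past the threshold under tedizolid passed. The adjusted p was then 0.668 for SOS, 0.451 for other amino acid synthesis, 0.59 for TCA cycle and glycolysis, 0.808 for flagella, and 0.395 for each of the other 10. rpsO went from 7743 ± 13.6 to 14400 ± 114.2 RPKM, rplM rose by 0.75 ± 0.04, rpsI by 0.67 ± 0.04 and rpsJ by 0.66 ± 0.04. ykgM and ykgO, zinc-independent copies of ribosomal proteins, changed by 1.19 and 1.27 in replicate 1 and −1.99 and −2.18 in replicate 2. Without tedizolid replicate 1 both were called lower (−1.50 and −1.57). The list's median was 0.39 and 0.36 in the tedizolid pairs, 0.29 in delpazolid pair 1 and −0.14 in the pair labelled delpazolid replicate 2.

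Heat-shock genes under the sigma factor RpoH fell: 21 of 27 passed lower and 2 higher, with a median of −1.13 (limma camera, adjusted p = 1.79e-07). hslV, a protease subunit gene, stood at −1.86 ± 0.08, the chaperone genes dnaK and groL at −1.25 ± 0.06 and −1.13 ± 0.08, while rpoH itself rose by 1.56 ± 0.07. Genes of the Cpx and sigma-E envelope stress responses fell as well, 18 of 26 lower and 4 higher (median −0.53; adjusted p = 0.00654). fkpA, a periplasmic isomerase gene, stood at −1.35 ± 0.08, bamD at −1.16 ± 0.10 and the sensor kinase gene cpxA at −1.37 ± 0.12. The phage-shock list rose, 6 of 7 genes higher (median 0.99; adjusted p = 7.82e-04). pspB stood at 1.13 ± 0.12, pspC at 1.04 ± 0.14, pspG at 1.18 ± 0.20 and pspA at 0.79 ± 0.10. Of the SOS genes, which respond to DNA damage, 8 of 22 passed higher and 1 lower (median 0.37; adjusted p = 5.14e-04). yebG rose by 1.46 ± 0.12, lexA by 1.33 ± 0.10 and recA by 1.04 ± 0.08. In the pair labelled delpazolid replicate 2 the medians of these 4 lists had the opposite sign: 0.547 for heat shock, 0.228 for envelope stress, −0.54 for phage shock and −0.234 for SOS.

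Amino acid operons preceded by a leader peptide fell: 30 of 38 genes passed lower and 0 higher, with a median of −0.87 (limma camera, adjusted p = 6.08e-08). ilvB stood at −1.98 ± 0.11, ilvN at −1.71 ± 0.10, thrB at −1.60 ± 0.08 and thrA at −1.51 ± 0.08. Other amino acid synthesis genes followed, 28 of 53 lower and 2 higher (median −0.52; adjusted p = 0.00179), among them lysA at −1.45 ± 0.11, aroA at −1.45 ± 0.11, serC at −1.40 ± 0.08 and asnA at −1.16 ± 0.10. Both lists had a median above 0 in the pair labelled delpazolid replicate 2 (0.0637 and 0.0733).

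Purine synthesis genes moved apart: 12 of 21 passed higher and 6 lower, with a median of 0.94 (limma camera, adjusted p = 9.74e-05). cvpA, the gene upstream of purF, rose by 2.22 ± 0.12, purC by 1.62 ± 0.10, purF by 1.30 ± 0.11, purE by 1.24 ± 0.12 and guaB by 0.76 ± 0.07. Genes of the mar, sox and rob regulons, which hold regulators and targets of multidrug tolerance, split 12 higher and 6 lower of 23, or 13 and 6 over the list alone (median 0.46; adjusted p = 0.00654). marA was at 127.9 RPKM without drug and 675.3 RPKM with it, marB by 2.21 ± 0.12 and soxR by 1.65 ± 0.18. The pump genes that remain in this strain went different ways: acrA rose by 0.82 ± 0.11 (limma, adjusted p = 2.44e-04), the outer-membrane channel gene tolC fell by 0.71 ± 0.09, acrD fell by 0.75 ± 0.27 (adjusted p = 0.0446), and acrF stood at 0.02 ± 0.26 (adjusted p = 0.955). acrD was not called without tedizolid replicate 1 (−0.90), without tedizolid replicate 2 (−0.60) or without DMSO replicate 1 (−0.65). Other multidrug efflux genes showed no common direction, 4 higher and 8 lower of 26 (adjusted p = 0.873).

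The lists of energy metabolism and motility shifted lower. In the ATP synthase and respiration list 28 of 34 passed lower and 2 higher, or 29 and 3 over the list alone (median −0.54; limma camera, adjusted p = 2.19e-05). sdhA stood at −0.89 ± 0.09, nuoF at −0.79 ± 0.08 and cyoE at −0.59 ± 0.06, while ndh, the alternative NADH dehydrogenase, rose by 0.68 ± 0.08. In the TCA cycle and glycolysis list 20 of 27 passed lower and 2 higher (median −0.42; adjusted p = 2.11e-04). Among them sucA stood at −0.82 ± 0.08, pgk at −0.78 ± 0.09, gapA at −0.72 ± 0.07 and acnB at −0.69 ± 0.08. Catabolic genes activated by CRP, the cyclic AMP receptor protein, passed lower in 32 of 57 cases and higher in 0, or 34 lower over the list alone (median −0.76; adjusted p = 2.19e-05). The maltose activator gene malT stood at −2.36 ± 0.14, gatD at −2.17 ± 0.17, gatA at −1.71 ± 0.11 and gatZ at −1.61 ± 0.10. Flagellar and chemotaxis genes passed lower in 23 of 48 cases and higher in 1, or 25 and 1 over the list alone (median −0.80; adjusted p = 0.00577). fliG stood at −2.41 ± 0.26, fliH at −2.29 ± 0.28, and the master regulator genes flhC and flhD at −2.15 ± 0.16 and −1.77 ± 0.15. Outer-membrane genes passed lower in 11 of 20 cases and higher in 3 (median −0.33; adjusted p = 0.0362, and 0.0667 in the 8-library fit). The porin gene ompF stood at −1.49 ± 0.09 and the protease gene ompT at −0.96 ± 0.07. In the pair labelled delpazolid replicate 2 the medians of these 5 lists lay above 0, between 0.0848 for the outer membrane and 0.278 for flagella.

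**Figure D3:**
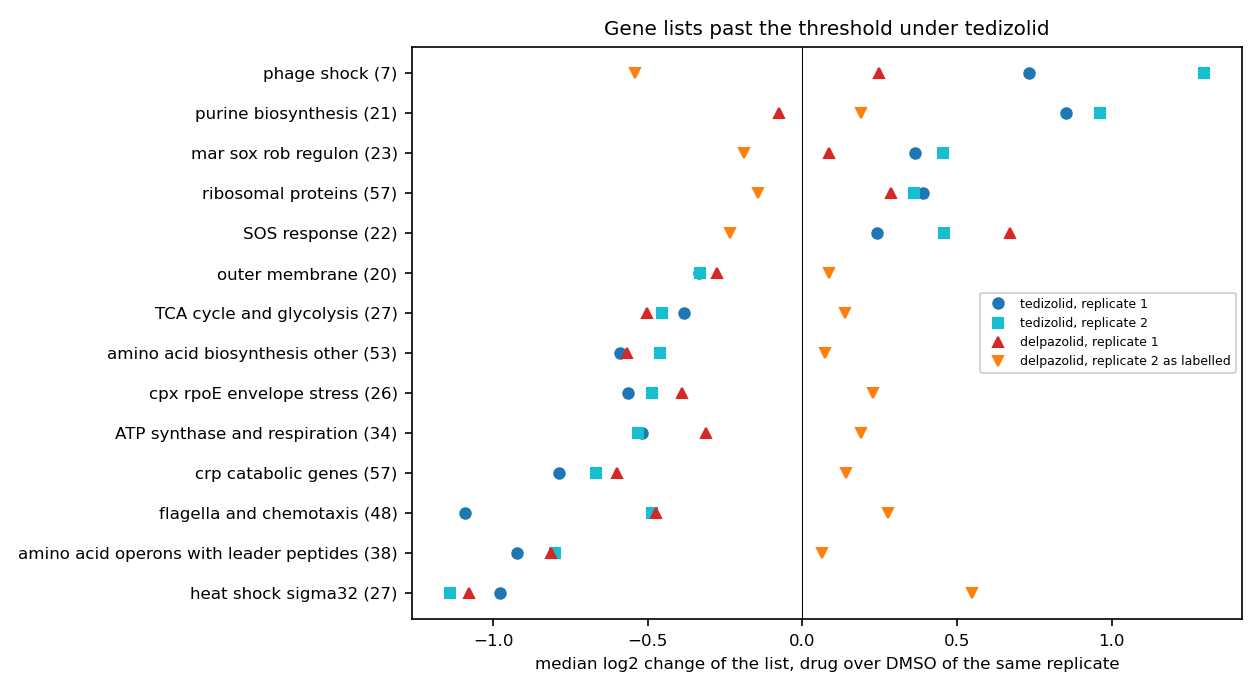
Median log2 change of the 14 gene lists past the threshold under tedizolid (horizontal axis), one point per replicate pair, with the number of measured genes in brackets. Both tedizolid pairs lie on the same side of 0 in each list, delpazolid replicate 1 does so in all but purine biosynthesis (−0.0764), and the pair labelled delpazolid replicate 2 lies on the other side in all but purine biosynthesis (0.191).

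The other 15 lists did not pass under tedizolid in the 4-library fit, although single members did. These were translation factors (10 higher and 5 lower of 19; limma camera, adjusted p = 0.0608), aminoacyl-tRNA synthetases (4 and 12 of 23; 0.0608), ribosome assembly (11 and 8 of 30; 0.0973), cold shock (7 and 4 of 19; 0.223), prophage genes (4 and 3 of 41; 0.282), RNA polymerase and termination (7 and 6 of 18; 0.424), and ribosome rescue and hibernation (6 and 5 of 12; 0.499). They further included pyrimidine synthesis (4 and 4 of 14; 0.685), Fur-controlled iron uptake (1 and 7 of 40; 0.705), fatty acid synthesis (4 and 9 of 23; 0.771), nucleoid proteins (4 and 6 of 15; 0.794), secretion (7 and 7 of 17; 0.794), RNA decay (3 and 5 of 14; 0.873), other multidrug efflux genes, and the RpoS general stress list (4 and 10 of 37; 0.911). Adjusted over the list alone, the counts differed by 2 or fewer in each direction. Within them the elongation factor gene tufB rose by 0.66 ± 0.05, the GTPase gene obgE by 1.60 ± 0.07, the cold-shock gene cspA by 0.71 ± 0.13 and the RpoS-controlled gene uspB by 1.14 ± 0.16. The release factor gene prfA stood at −1.19 ± 0.17, the cold-shock family gene cspE at −1.66 ± 0.06, the synthetase genes serS and pheS at −0.72 ± 0.07 and −0.68 ± 0.07, and rmf, the hibernation factor gene, at −0.64 ± 0.19. rmf was not called without tedizolid replicate 1 (−0.37), with median-ratio scaling (−0.50), with limma-voom (−0.64) or without the intensity trend, and cspA was not called without the trend.

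The second comparison asked the same of delpazolid. As labelled, limma called 0 of 4026 genes in the 8-library fit (66 at an unadjusted p under 0.05), 0 in the fit of the 4 delpazolid experiment libraries (31) and 0 with limma-voom on recovered reads (44). In delpazolid pair 1, 1722 of the 1784 genes called under tedizolid (96.5%) changed in the direction they had under tedizolid, with a slope of 0.817. In the pair labelled replicate 2, 1526 of them (85.5%) changed in the opposite direction, with a slope of −0.366. Without DMSO replicate 2 the 8-library count was 23, with 4 higher and 19 lower, and without any one of the other 7 libraries it was 0. Still, 6 lists passed (limma camera, 8-library fit; adjusted p = 0.706 with an estimated correlation for each), with 0 members called, also over the list alone. TCA cycle and glycolysis had a median of −0.20 (adjusted p = 3.25e-05), leader-peptide amino acid operons −0.35 (1.20e-05), other amino acid synthesis −0.21 (1.41e-04), CRP catabolic genes −0.22 (2.95e-04), aminoacyl-tRNA synthetases −0.14 (4.79e-04), and ribosomal proteins 0.10 (7.82e-04). In each of these 6 lists the medians of the delpazolid pairs had opposite signs, such as −0.351 and 0.0565 for synthetases. fry passed none of the lists (adjusted p = 0.965 at the lowest, 4-library fit).

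No single gene passed, so the 5 genes each way with the smallest p that moved alike in both pairs were taken (limma, adjusted p = 0.998 for each). The larger values were yjdO at 1.68 ± 0.45 (2.39 and called without DMSO replicate 2), yaiY at 1.22 ± 0.30, pyrL, the leader peptide of the pyrBI operon, at 0.85 ± 0.26, the copper-responsive regulator gene cusR at 0.81 ± 0.25 and yihI at 0.76 ± 0.24. The smaller ones were ygeI at −1.72 ± 0.50, hycF at −1.003 ± 0.289, eutN at −0.96 ± 0.31, eutQ at −0.89 ± 0.28 and ygcP at −0.75 ± 0.26; yaiY, yjdO, hycF, ygeI, eutQ, eutN and ygcP had means under 10 RPKM in at least 1 of the groups. pyrB, the first enzyme gene after pyrL, stood at 0.04 ± 0.25. Of the genes followed in every comparison, acrA stood at 0.01 ± 0.27, acrD at 0.20 ± 0.35, acrF at 0.37 ± 0.29, tolC at −0.13 ± 0.27, rmf at −0.03 ± 0.27 and cspA at 1.15 ± 0.46.

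Without both libraries labelled replicate 2, an alternative added after the data were seen, limma called 1228 genes under delpazolid, 480 higher and 748 lower. That fit has 1 delpazolid and 1 DMSO library and takes its spread from the tedizolid experiment. In simulated data with the spread measured in the delpazolid groups that fit called 1018 of 3786 unchanged genes, and with the tedizolid experiment's spread 17. The first spread is the gap between replicates 1 and 2, so it includes the libraries left out, and was drawn as independent noise. The count of the fit holds only if delpazolid cultures vary as little as the others, which was not measured. There, 34 of 57 ribosomal protein genes passed higher and 0 lower (36 and 0 over the list alone; camera, adjusted p = 3.27e-15). Of 27 heat-shock genes 18 passed lower and 2 higher (19 and 2 over the list alone; adjusted p = 1.67e-07). With an estimated correlation the adjusted p was 0.478 for both lists.

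The third comparison set the drugs against each other, as the response to tedizolid minus the response to delpazolid. Purine genes led it: of the genes that differed alike in both replicate numbers xanP had the smallest p, with a difference of 1.97 ± 0.84 (half-width of the 95% interval), followed by purC at 1.41 ± 0.67, purT at 1.88 ± 0.91 and purM at 2.08 ± 1.02, each higher in the tedizolid response. limma called 0 of 4026 genes all the same (adjusted p = 0.744 for each of these; 226 genes at an unadjusted p under 0.05; 254 with limma-voom, which also called 0). eutN stood at 1.80 ± 0.99, on 1 to 7 reads per library. On the other side were mreC at −1.94 ± 1.08, yojI at −1.76 ± 0.97 and yodB at −1.76 ± 1.19. ykgR stood at −2.79 ± 1.76, on 0 to 6 reads per library, so its value and that of eutN also lean on the pseudocount. tnaC, the leader peptide of the tryptophanase operon, had a fitted difference of −4.29 ± 2.62, which depends on the pseudocount, since it was at 0 RPKM in both tedizolid libraries and on 5 reads at most in any library. tnaA, the enzyme gene after tnaC, stood at −0.03 ± 1.12. The count was 457 without DMSO replicate 1 of the delpazolid experiment, 114 higher and 343 lower, and 0 without any one of the other 7 libraries.

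For the efflux and stress genes followed throughout, the interval of the difference in the 8-library fit included 0: acrA 0.81 ± 0.88, acrD −0.95 ± 1.12, acrF −0.35 ± 0.94, tolC −0.58 ± 0.88, rmf −0.60 ± 0.88 and cspA −0.44 ± 1.49. Without the libraries labelled replicate 2 of the delpazolid experiment, the difference was 0.51 ± 0.43 for acrA and −1.40 ± 0.52 for cspA. The spread in that fit comes from the tedizolid experiment alone, so these 2 intervals hold no variation between delpazolid cultures. The difference of acrA was called without DMSO replicate 1 of that experiment, at 1.20. The intervals do not exclude differences as large as their far bounds, so the drugs were not shown to act alike on these genes. Across the 4026 genes the responses correlated at r = 0.508 (Spearman's rho = 0.556), and delpazolid changes had a slope of 0.223 on tedizolid changes; the drugs have separate DMSO libraries. Without the libraries labelled replicate 2 of the delpazolid experiment, r was 0.81, rho 0.802 and the slope 0.807. Calls for both drugs in that fit share the spread of the tedizolid experiment, so independent lists do not give their chance level. In that fit 398 genes were higher and 705 lower under both drugs, against 75.5 and 214 for independent lists, and 2 were called in opposite directions.

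The difference between the responses passed in 11 lists at the preset correlation (limma camera, 8-library fit, with no member called). With an estimated correlation the adjusted p was 0.713 for purine synthesis, 0.825 for SOS, 0.846 for flagella, 0.895 for leader-peptide operons and 0.795 for each of the other 7. Higher in the tedizolid response were ribosomal proteins, with a median difference of 0.26 (adjusted p = 1.14e-11), purine synthesis, 0.75 (1.68e-09), phage shock, 0.84 (4.71e-06), mar, sox and rob, 0.41 (0.00109), and SOS, 0.27 (0.00676). Lower were heat shock, −0.79 (3.68e-04), respiration, −0.48 (0.00109), flagella, −0.60 (0.0012), CRP catabolic genes, −0.56 (0.0012), Cpx and sigma-E, −0.42 (0.0171; 0.0569 with the replicate block), and leader-peptide operons, −0.54 (0.0194). Adjusted over the list alone, 12 purine and 4 phage-shock genes passed higher and 0 genes of the other 9 lists passed. Without the libraries labelled replicate 2 of the delpazolid experiment, 6 of the 11 lists no longer passed: heat shock, respiration, flagella, CRP catabolic genes, leader-peptide operons and SOS, whose median difference turned to −0.0358. Ribosomal proteins passed there with a median difference of 0.0629 and a mean of −0.0028; 0 of their genes passed higher and 2 lower (0 and 6 over the list alone). In each of the 11 lists the pair labelled delpazolid replicate 2 had a median change of opposite sign to that of delpazolid pair 1, in the purine list 0.191 against −0.0764.

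**Figure D4:**
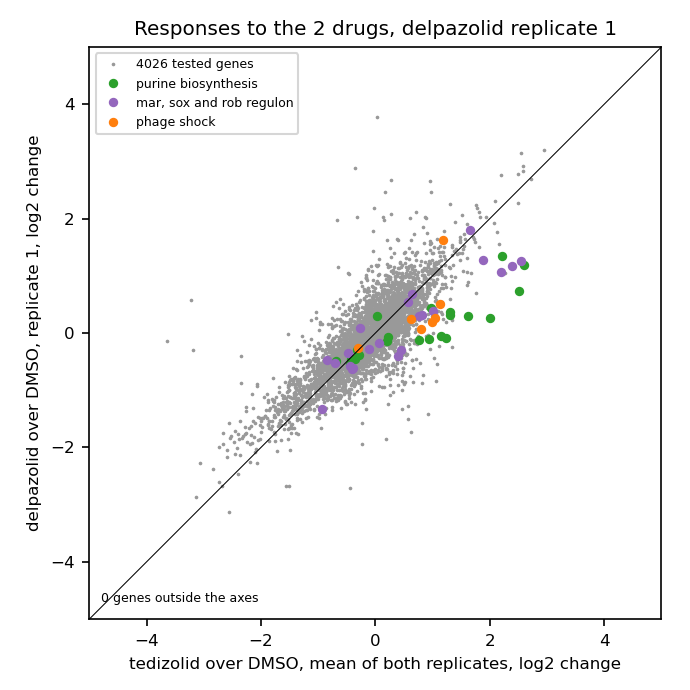
Change under delpazolid in replicate 1 alone (vertical, log2 ratio of RPKM + 1) against the mean change under tedizolid (horizontal); each point is one of 4026 tested genes, the line marks equal change, and 3 gene lists are coloured. Across the 4026 genes the 2 axes correlate at 0.81. Over the 1784 genes called under tedizolid, and so chosen by their horizontal values, they correlate at 0.914. Most purine genes lie below the line.

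The last comparison set the DMSO libraries of the 2 experiments against each other, to measure how far the experiments differ without drug. The largest difference was that of zinT, a periplasmic zinc-binding protein gene (BW25113_1973). It was at 1612 and 2568 RPKM in the tedizolid experiment and at 14.5 and 10.8 RPKM in the delpazolid experiment, a log2 difference of 7.23 ± 0.39 (limma, adjusted p = 1.10e-04). znuA, znuB and znuC, which encode a zinc importer, were higher by 4.33 ± 0.27, 2.28 ± 0.25 and 2.10 ± 0.28, and ykgM and ykgO by 5.95 ± 0.61 and 5.46 ± 0.64. The endopeptidase gene mepM (3.29), the lysozyme inhibitor gene pliG (3.12) and yodB (2.52) were also higher, and zntA, the zinc exporter gene, was lower by 2.95 ± 0.27. These were the 10 genes called, 9 higher and 1 lower of 4026 (165 at an unadjusted p under 0.05). With the replicate number as a block limma called 0 genes (85 at an unadjusted p under 0.05, smallest adjusted p = 0.0762). That block sets the fitted replicate 1 levels of the DMSO groups against each other, not the group means. It thus changes the comparison as well as the degrees of freedom. Each of the 10 kept its direction with the block, with zinT at 7.23 and zntA at −2.87, on 2 residual degrees of freedom in place of 4. The drug libraries shared the difference: zinT stood at 883.8 and 396.6 RPKM under tedizolid and at 5.73 and 5.32 RPKM under delpazolid.

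In this comparison 12 lists passed (limma camera; adjusted p between 0.542 and 0.708 with an estimated correlation). Fur-controlled iron uptake (adjusted p = 7.45e-11), leader-peptide operons (5.32e-08), heat shock (1.21e-06), CRP catabolic genes (4.52e-04), other amino acid synthesis (0.00573) and respiration (0.0121) were higher in the tedizolid experiment. Ribosomal protein genes (9.12e-12), SOS (9.80e-07), mar, sox and rob (4.52e-04), translation factors (0.00573), cold shock (0.0347) and purine synthesis (0.0482) were lower. With the replicate number as a block 5 of the 12 no longer passed: respiration (0.249), SOS (0.0682), other amino acid synthesis (0.987), mar, sox and rob (0.0682) and purine synthesis (0.455). These values too compare fitted replicate 1 levels, not group means. Without the libraries labelled replicate 2 of the delpazolid experiment, 2 of the lists passed, iron uptake (5.87e-17) and heat shock (2.82e-11). The count of genes was 584 without DMSO replicate 1 of the delpazolid experiment and 5 without DMSO replicate 2 of it; it was 4 and 2 without DMSO replicates 1 and 2 of the tedizolid experiment, and 6 without either delpazolid library. Without the block, zinT and znuA passed without any one library, and each of the other 8 genes failed without at least 1.

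**Figure D5:**
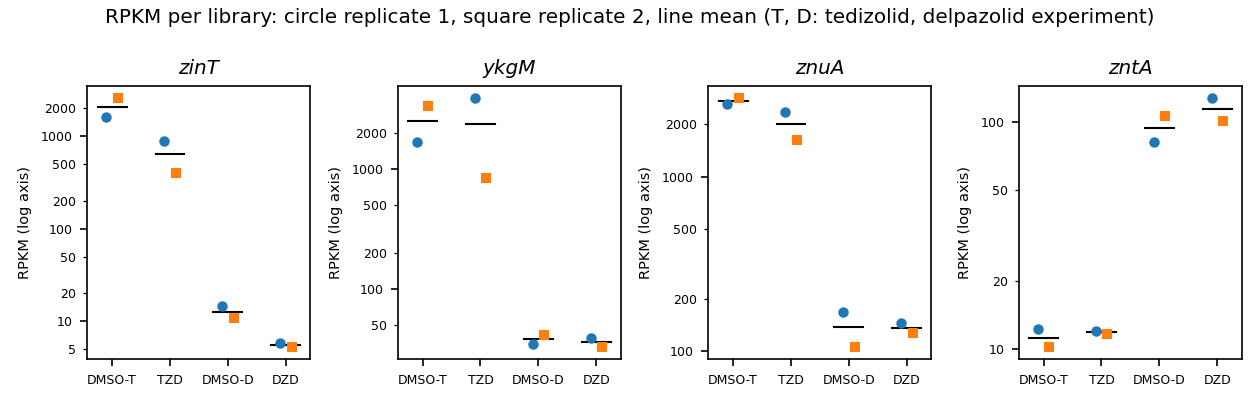
RPKM of 4 genes of zinc supply in each library on a log axis (circle, replicate 1; square, replicate 2; line, mean), with groups named as in the plot of 8 genes. zinT, ykgM and znuA are higher and zntA is lower in all 4 libraries of the tedizolid experiment than in all 4 of the delpazolid experiment.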

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

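The tests reported here without the libraries labelled replicate 2 of the delpazolid experiment, and all 4 tests that weigh explanations for those libraries, were chosen after the result was seen; the tests on purine genes were written before theirs.

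The difference between the drugs' responses passed in 11 gene lists (limma camera, 8-library fit), which marks them for a closer look: ribosomal proteins (adjusted p = 1.14e-11), purine synthesis (1.68e-09), phage shock (4.71e-06), heat shock (3.68e-04), mar, sox and rob (0.00109), respiration (0.00109), flagella (0.0012), CRP catabolic genes (0.0012), SOS (0.00676), Cpx and sigma-E (0.0171) and leader-peptide operons (0.0194). With an estimated correlation the adjusted p lay between 0.713 and 0.895. Without the libraries labelled replicate 2 of the delpazolid experiment, 5 of these passed: purine synthesis (4.03e-18), mar, sox and rob (2.12e-05), phage shock (4.70e-04), Cpx and sigma-E (0.0105) and ribosomal proteins (0.0373). Ribosomal proteins had a median difference of 0.0629 there in place of 0.26, a mean of −0.0028, and 0 genes higher and 2 lower (0 and 6 over the list alone), so their single genes that passed went against the direction of the list test. The other 6 did not pass, and SOS turned direction, with a median difference of −0.0358 in place of 0.274. In that fit aminoacyl-tRNA synthetases (1.45e-04), TCA cycle and glycolysis (0.00263), iron uptake (0.0105) and secretion (0.0105) passed as well. With an estimated correlation no list passed there, and the adjusted p was 0.396 for the purine, mar and synthetase lists.

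Single genes that differed between the drugs in that fit numbered 13 (limma, adjusted p between 0.0267 and 0.0492; 320 genes at an unadjusted p under 0.05). Higher in the tedizolid response on the log2 scale were xanP (1.78), purM (1.41), purE (1.33), purC (1.32), marR (1.29), marA (1.22), pheL, the leader peptide of pheA (1.11), and guaB (0.88). Lower were tnaC (−3.80, which depends on the pseudocount, with 0 RPKM in both tedizolid libraries), cspA (−1.40), infA, an initiation factor gene (−0.85), rplU (−0.62) and rpmA (−0.56). Of these, pheL (−0.91), rplU (0.11) and rpmA (0.15) had the opposite sign in the 8-library fit. pheA stood at −0.06 ± 0.41 and tnaA, after tnaC, at −0.28 ± 1.16 (half-width of the 95% interval). In simulated data with the spread of the delpazolid groups and no difference, this fit called 598 of 4026 genes, and with the spread of the tedizolid experiment 1. The first spread includes the libraries left out and was drawn as independent noise, so it does not estimate ordinary variation between cultures. The genes named here rest on delpazolid cultures varying as little as the others, which was not measured.

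The first pattern weighed is replicate 2 of the delpazolid experiment. On an axis from DMSO replicate 1 (0) to delpazolid replicate 1 (1), over the 1784 genes called under tedizolid, the library labelled DMSO replicate 2 lay at 0.972 (95% of gene resamplings 0.932 to 1.02) and the library labelled delpazolid replicate 2 at 0.49 (0.459 to 0.522), while the tedizolid libraries lay at 1.2 and their DMSO libraries at −0.0675 and −0.0109. The first position argues only against both libraries being in the untreated state, and leaves open whether the drug culture responded. The shallower of these libraries, with 6.80 M estimated reads against 4.76 M in the shallowest of the other 6, argues against low depth. In both, zinT, ykgM, ykgO and znuA were at most 7.82% of their lowest level in the tedizolid experiment. For the drug-labelled library this argues against an exchange with that experiment. For the DMSO-labelled one it cannot decide, since the genes were picked by their difference between DMSO groups that include it. A complete exchange of the labels stays open, and no value here decides. The DMSO-labelled library lies close to delpazolid replicate 1, while the drug-labelled one lies midway. The axis took its genes and their weights from the tedizolid changes, so the positions of that experiment's libraries are partly set by this choice. DMSO replicate 1 is 0 by definition, so no independent untreated culture gives the range to expect. A partial mixing, or a response under way in the control, was not tested. The labels are kept as given, although the descriptions name the replicate 1 column for DMSO replicate 2 as well.

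The second pattern is the purine and mar lists, whose medians lay higher in the tedizolid response than in delpazolid replicate 1; of single genes, 5 of 21 and 2 of 23 passed higher (12 and 4 over the list alone) and 0 lower. The purine list's median difference was 0.877 without the libraries labelled replicate 2 and 0.904 under median-ratio scaling, which argues against the scaling of the libraries for that list. Against delpazolid replicate 1 it was 0.838 for tedizolid replicate 1 and 0.782 for tedizolid replicate 2, but both values share that pair, and the pair labelled replicate 2 (0.662 and 0.83) ran opposite to it over all genes, so dependence on a single delpazolid pair stays open. The bound set beforehand for these values could be met whether or not the pair was the source. A difference in how the drugs act on these genes is a hypothesis that may account for it; the experiment is confounded with the drug, and between DMSO groups both lists were lower in the tedizolid experiment (adjusted p = 0.0482 and 4.52e-04; 0.791 and 0.449 without the libraries labelled replicate 2), so a difference between experiments stays open.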

How the results depend on the processing

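The fits without both delpazolid libraries labelled replicate 2, with limma-voom, with array weights, with a crossed pairing, and the settings within the 4-library tedizolid fit were chosen after the data were seen. The cause of a changed value was not tested unless given.

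The 8-library count of genes changed by tedizolid, 3, depended on the spread given to the delpazolid experiment. It was 1784 with its own 4 libraries, 1785 without the libraries labelled replicate 2, 1732 with array weights and 529 with a crossed pairing. It was 1 without the intensity trend and with a pseudocount of 0.1, and 6 with all 4 DMSO libraries as one control and with limma-voom. It was 0 with the replicate block (936 genes at an unadjusted p under 0.05) and 0 for a 1.5-fold minimum (326). Without single libraries it ran from 0 to 989, the higher values coming without either DMSO library of the delpazolid experiment. The 4-library count of 1784 ran from 1352 to 1968 without single libraries, and was 510 for a 1.5-fold minimum. Other settings of that fit called 1414 without the trend (1350 of them shared), 2077 with the block (1784 shared, so the block lost no call), 1780 with median-ratio scaling (1558 shared) and 1776 with limma-voom (1696 shared).

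The count of 0 genes for delpazolid stayed 0 in limma under every setting except without both libraries labelled replicate 2 (1228) and without single libraries, where it ran from 0 to 23 (66 genes at an unadjusted p under 0.05 in the leading fit). The difference between the drugs, 0 genes (226), was 13 without both libraries labelled replicate 2 and ran from 0 to 457 without single libraries. The 10 genes between DMSO groups became 0 with the replicate block (85 at an unadjusted p under 0.05; smallest adjusted p = 0.0762), 5 with array weights, 4 with a crossed pairing, and 2 to 584 without single libraries. Between DMSO groups, the block and the crossed pairing compare fitted levels of single replicates, not group means, so those counts answer a different comparison. The correlation of the drugs' responses, 0.508, was 0.604 at a filter of 5 RPKM and 0.81 without both libraries labelled replicate 2.

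With an estimated correlation, 0 lists passed in any comparison, against 13 for tedizolid in the 8-library fit, 14 in the 4-library fit, 6 for delpazolid, 11 for the difference and 12 between DMSO groups. Without both libraries labelled replicate 2, 2 lists passed between DMSO groups. Between DMSO groups the replicate block compares fitted replicate 1 levels, not group means. It ended the calls of respiration (camera, adjusted p = 0.249), SOS (0.0682), other amino acid synthesis (0.987), mar (0.0682) and purine synthesis (0.455). It added flagella (0.0013) and phage shock (0.0367). Median-ratio scaling ended respiration (0.109) and cold shock (0.0567) and added flagella (0.0486). In fry, 4-library fit, SOS (0.128) and flagella (0.176) did not pass for tedizolid, aminoacyl-tRNA synthetases (0.00315), translation factors (0.019) and nucleoid proteins (0.0159) passed, unlike in camera, and no list passed for delpazolid (0.965 at the lowest).

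Counting each named gene under each alternative as a case, the direction reversed in 6 cases for tedizolid, 13 for delpazolid and 15 for the difference, while 1225, 347 and 478 kept direction and side of the threshold. A call was lost in 124 cases for tedizolid, most of them in the 8-library fit, and in 55 between DMSO groups, and gained in 3 for tedizolid, 8 for delpazolid and 24 for the difference. For tedizolid, left-out libraries took acrF from −0.16 to 0.21, ykgM from −1.50 to 0.70 and ykgO from −1.57 to 0.66. For delpazolid they took acrA from −0.39 to 0.40, acrD from −0.28 to 0.68, tolC from −0.55 to 0.30, rmf from −0.16 to 0.10 and pyrB from −0.071 to 0.14. For the difference they took pheL from −2.41 to 0.59, rpmA from −0.32 to 0.62, rplU from −0.37 to 0.59, cspA from −1.32 to 0.45 and tnaA from −0.43 to 0.37. Without both libraries labelled replicate 2, acrD under delpazolid was −0.27, pyrB −0.12, and the differences of pheL, rpmA and rplU were 1.11, −0.56 and −0.62. acrA under delpazolid was −0.0021 with median-ratio scaling and −0.016 with limma-voom, pyrB −0.022 with all 4 DMSO libraries, and the difference of tnaA 0.10 with median-ratio scaling and 0.0012 with a pseudocount of 10.

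The planned tests for counts were not run, since the values are RPKM. Leaving out a library leaves its group with 1 library, assumed to vary like the others. Depth limits genes with few reads, such as the leader peptides trpL and tnaC.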

Other observations

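The operon slopes for delpazolid and the operons given as examples were chosen after the tedizolid result was seen; the other operon tests were written before theirs.

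Under tedizolid, genes late in an operon fell further, on average over the operons listed, than genes early in it. In the rpoE operon the first gene, rpoE, stood at 0.37 ± 0.11 and the last, rseC, at −2.66 ± 0.18 (log2, SE). gmk, the first gene of the spoT operon, stood at 0.73 ± 0.08 and recG, the last, at −2.47 ± 0.17. In the mre operon mreB stood at −0.16 ± 0.08 (limma, adjusted p = 0.149) and rng at −1.61 ± 0.17. rpoE was not called without tedizolid replicate 1 (0.30) or without the intensity trend, and mreB was called without DMSO replicate 2 (−0.26). Other operons fell along their whole length: thrA and thrC stood at −1.51 and −1.34, and dppA and dppF at −1.81 and −1.44.

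This is the third pattern weighed. Over 51 operons and 290 genes, from 57 operons listed before the test, the mean slope of log2 change on gene position was −0.163 ± 0.033 per gene (SE), negative in 43 operons (sign-flip permutation test, 100000 permutations, two-sided p = 1e-05, the smallest they can give; adjusted p = 1.2e-05 over 7 such tests). This p is over operons of the same cultures and does not measure the spread between cultures. The slope between the DMSO libraries of the same experiment was −0.0247 (p = 0.042 by the same permutation test), which argues against a trend among untreated libraries as the whole cause. After removal of trends on gene length and level the mean slope was −0.152, which argues against these as the whole cause. The median slope was −0.101 before that removal and −0.0725 after it, with 39 operons negative after it. The rpoE and spoT examples had the steepest slopes (−1.04 and −0.977), so they are not typical. The mean slope without that removal was −0.153 and −0.174 in the tedizolid pairs, −0.131 in delpazolid pair 1 and 0.103 in the pair labelled delpazolid replicate 2. A candidate explanation is that loss of translation ends transcription within operons early, a hypothesis that these data do not test and that levels of nascent RNA along operons would decide; faster decay of the late part of a message and internal promoters stay open as well.

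In the authors' deposited table of translation efficiency, the smallest adjusted p was 0.0812 for tedizolid over DMSO (4034 genes) and 0.108 for delpazolid over DMSO (4024 genes), so 0 genes lay under 0.05 in either. This does not show that efficiency was unchanged. The RNA values deposited with the delpazolid comparison include the pair labelled replicate 2, which ran opposite to the other pairs. How that pair entered the authors' test was not examined.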
